A study of Homo sapiens with 6 samples.

How the data were processed

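REC-1 mantle cell lymphoma cells were sampled as 3 parental libraries (DMSO, 24 h) and 3 ibrutinib-resistant libraries (100 nM ibrutinib, 24 h), all after IgM crosslinking for 5 min, and libraries were made with a stranded total RNA kit, per the labels' protocols. The deposited files hold raw counts of fragments per gene. Per the file headers, the authors counted them with featureCounts 2.0.1 in paired mode over exons grouped by gene, with forward strandedness, a fragment being counted for every gene it overlapped, on an Ensembl GRCh37 release 75 annotation from which ribosomal RNA and mitochondrial genes had been removed. The submitters' processing notes name STAR 2.5, Subread 1.5.1 and featureCounts, with GRCh37 and hg19 as builds, so header and notes give different versions. Counting by strand keeps antisense genes apart, while genes with overlapping exons on the same strand (5284 of 57209) take the same fragments and are treated as uncertain where named.

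Groups and replicate numbers were taken from the labels. Total counts ranged from 35721845 to 44206000, and 3 counts, taken as the limit for a group at 0, came to between 0.0679 and 0.084 CPM per library. Intervals and floors cover counting error only. Gene symbols came from a table of identifiers and biotypes from GENCODE v29, matched by identifier; 51789 genes had both, with 97.57% of counts. Coordinates are those of the files (GRCh37).

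Counts were tested in R 4.3.3 with edgeR 4.0.16: genes kept by filterByExpr (minimum count 10), TMM factors (0.984 to 1.01), robust quasi-likelihood fit and test of resistant against parental libraries, two-sided, with Benjamini-Hochberg adjustment over all tested genes at 0.05. A subset with an absolute log2 fold change of at least 1 was counted apart. The standard error is the size of the log2 fold change over the square root of F. The square root of the common dispersion was 8.30%. An exact permutation test of 3 against 3 cannot go below 0.10 and was not used.

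The 37 gene lists were fixed before the data were examined, and those with at least 5 tested genes were tested with camera (limma 3.58.1, correlation 0.01), adjusted over the lists: B cell receptor signalling, NF-kB targets, immediate early genes, MAPK feedback, NOTCH targets, B cell identity, plasma cell, mantle cell lymphoma, MHC class II, MHC class I presentation, interferon-stimulated, BCL2 family and death receptors, homing and adhesion, PI3K-AKT-mTOR, MYC and ribosome biogenesis, DNA replication, mitosis, ATF4 and integrated stress response, unfolded protein response, heat shock, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded, cholesterol synthesis, glutamine and one-carbon, ABC transporters, p53 targets, enhancer and looping machinery, noncanonical NF-kB and TNF receptors, ribosomal proteins, histones, and T cell, NK cell, myeloid, stromal, erythroid and epithelial markers. Of 903 list members, 880 had an identifier in the files.

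Genes were named by a rule fixed at the same time: the 10 highest and 10 lowest log2 fold changes among protein-coding genes past the threshold, with a mean of at least 5 CPM in the higher group and no overlap of the 3 and 3 values; the 3 rising and 3 falling of these with the smallest p; BTK, PLCG2, CD79A, CD79B, MYC, CCND1, SOX11 and NOTCH1; and for each list up to 4 members past the threshold with the largest changes. Some of these genes are not reported here. CD3E, CD68 and the genes of the closing observations were picked after their values were seen.

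Alternatives were DESeq2 1.42.0, limma-voom, median-ratio factors, no composition factor, no filter and a stricter filter (1 CPM in 3 libraries), protein-coding genes only, no structural RNA genes, the replicate number as a block, each library left out, thinning to the smallest total, a null of 1.5-fold, camera with estimated correlation and fry. A further pair was chosen after seeing the data: leaving out genes that share exons, and testing each gene against the median of its 50 nearest tested protein-coding neighbours. In DESeq2 and against neighbours, lists were tested with cameraPR on the statistics of the genes instead of camera on the counts.

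The tests were checked on simulated counts with 200 genes changed in both directions at a dispersion of 0.02. Of the genes changed 1.5-fold, 2-fold and 4-fold, edgeR recovered 34.3%, 86.6% and 100%, and called 9 of 17017 unchanged genes (0.053%). The data had far more changed genes and a smaller common dispersion, so these rates need not hold for them. The search for shifted windows found 5 of 5 planted windows among 395 and 1 other. Subtracting neighbours kept 0.58 of a planted list shift of 0.6.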

Results

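Gene expression was measured by strand-specific total RNA sequencing in REC-1, an established human mantle cell lymphoma line, in a parental form and in a form resistant to ibrutinib, a covalent inhibitor of the kinase BTK. The 3 parental libraries came from cells kept in DMSO for 24 h and the 3 resistant libraries from cells kept in 100 nM ibrutinib for 24 h, and in both groups the B cell receptor was crosslinked with IgM for 5 min before lysis. Deposited counts were available for 57209 genes. Total counts were 40203290, 43468119 and 44206000 in parental replicates 1, 2 and 3 and 41811601, 35721845 and 40746545 in resistant replicates 1, 2 and 3. The first principal component of the log2 CPM (counts scaled to the library total) held 89.8% of the variance and separated the groups, with parental libraries between -42.2 and -40.1 and resistant libraries between 40.5 and 41.3. The second, with 5.20% of the variance, set parental replicate 3 at -17.3 apart from parental replicates 1 and 2 at 8.52 and 8.54. Parental replicates 1 and 2 were closer to each other than any other pair within a group: the chi-square of their counts was 4.72 per gene, against 39.4 and 41.7 for the pairs with parental replicate 3 and 11.5 to 19.7 for the resistant pairs. It was above the 1 expected from sampling noise, and every library was kept as a separate sample.

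The comparison asks which transcripts differ between resistant cells under drug and parental cells under vehicle. In the resistant cells the transcripts of the ephrin receptor EPHA3, the protocadherin FAT4, the cholesterol exporter ABCA1 and the NOTCH ligand JAG1 (uncertain, as it shares exons with another gene) were far more abundant, while those of the RNA helicase DDX3X, the transcription factor ETV1, the Fc receptor-like gene FCRL4 and the interleukin 7 receptor chain IL7R were far less abundant. EPHA3 was at 0.0394 ± 0.0355 CPM (SD, n = 3) in parental cells and 27.1 ± 0.936 CPM (SD, n = 3) in resistant cells, a log2 fold change of 9.34 (SE 0.21, edgeR adjusted p = 2.09e-11). DDX3X (ENSG00000215301, GRCh37 chromosome X, 41192651 to 41223725) went the other way, from 368 ± 7.11 to 13.1 ± 0.285 CPM (SD, n = 3 each), a log2 fold change of -4.81 (SE 0.07, adjusted p = 1.32e-12), and had the smallest p among the falling genes named by rule. ETV1, an ETS factor, fell from 332 to 18.1 CPM (log2 fold change -4.20, SE 0.07), and FCRL4 fell from 256 to 13.7 CPM (log2 fold change -4.23, SE 0.07).

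Of 17247 genes tested, 10169 (59.0%) passed an adjusted p of 0.05, 5132 higher and 5037 lower in resistant cells. At least 2-fold changes were found for 3011 of them, 1602 higher and 1409 lower, and 777 protein-coding genes changed at least 4-fold, 426 higher and 351 lower. The 3 values of one group did not overlap the 3 of the other for 11025 genes (63.9%), against 10% expected by chance. Against a 1.5-fold change as the null hypothesis, 3599 genes passed.

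Among the 10 protein-coding genes with the highest fold changes, MDFI, an inhibitor of myogenic factors, and the matrix gene MFAP4 had no counts in any parental library. Set against a floor of 3 counts per library, they were at least 91.0-fold and at least 84.5-fold higher in resistant cells, with MDFI at 6.46 ± 0.766 CPM (SD, n = 3). MMRN1, with 3 counts in the parental group, was higher by a ratio of 321 (95% counting interval 110 to 1560). FAT4 reached 30.8 CPM (log2 fold change 8.32, SE 0.18) and PPP1R9A 9.37 CPM (7.80, SE 0.27). MAGEA3, a cancer-testis antigen, rose to 10.5 CPM (7.17, SE 0.19), a value that is uncertain because near-identical MAGEA copies can take each other's fragments. ABCA1 rose from 0.533 to 42.1 CPM (6.31, SE 0.16), the mesenchymal factor TWIST2 to 5.99 CPM (6.21, SE 0.25) and FAM13A to 12.8 CPM (6.02, SE 0.20). By smallest p, the rising genes were PSD3 (from 1.75 to 74.0 CPM), the neuronal pentraxin NPTX2 (from 0.497 to 30.8 CPM) and JAG1 (log2 fold change 5.30, SE 0.11). PSD3 and JAG1 each share exons with another gene on the same strand, and a fragment there was counted for both.

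At the other end, the monocarboxylate transporter family gene SLC16A14 had 2 counts in the resistant group and was higher in parental cells by a ratio of 775 (95% counting interval 214 to 6400). PHEX, an endopeptidase of phosphate metabolism, fell from 129 to 0.268 CPM (log2 fold change -8.92, SE 0.16), and IL7R from 13.5 to 0.0327 CPM (-8.50, SE 0.27). The adhesion gene CADM1 fell from 76.6 to 0.715 CPM (-6.74, SE 0.16) and the transporter ABCA9 from 12.9 to 0.133 CPM (-6.53, SE 0.20). FBLN2 (-7.27), EYA4 (-7.22), NLGN4X (-7.05) and CTXN3 (-7.03) also fell. KLRK1, a killer lectin-like receptor (-6.59, SE 0.19), shares exons with a read-through gene and is uncertain.

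**Figure D1:**
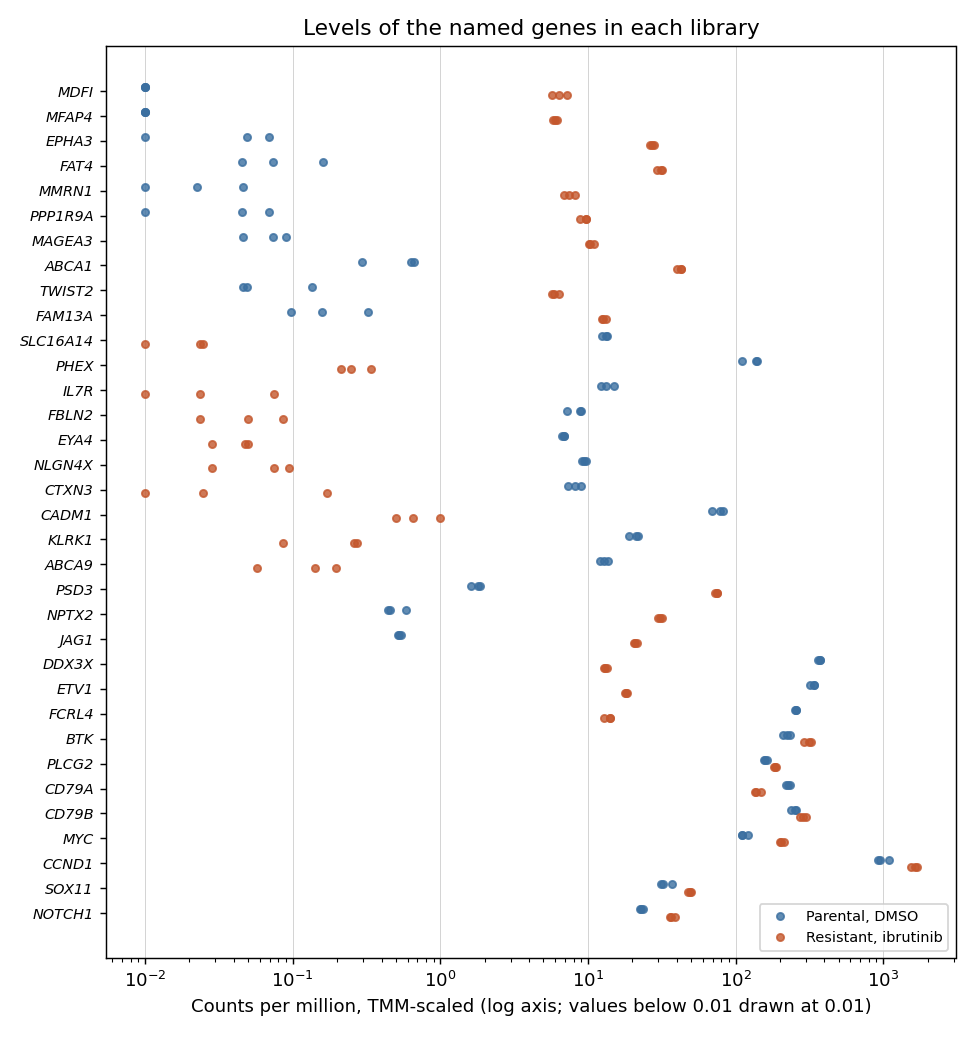
TMM-scaled CPM of the named genes, 1 point per library, 3 parental (blue) and 3 resistant (red) libraries, on a log axis with values below 0.01 drawn at 0.01. DDX3X sits near 368 CPM in parental and 13.1 CPM in resistant libraries, while BTK differs by 0.48 on the log2 scale.

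BTK rose from 223 ± 13.6 to 310 ± 16.6 CPM (SD, n = 3 each; log2 fold change 0.48, SE 0.07, adjusted p = 8.02e-05). PLCG2, the phospholipase downstream of BTK, had a log2 fold change of 0.22 (SE 0.06, adjusted p = 0.00614), and CD79B one of 0.21 (SE 0.07, adjusted p = 0.0148). CD79A, the partner of CD79B in the receptor, fell by 0.69 on the log2 scale (SE 0.06, adjusted p = 1.63e-06). MYC (0.84, SE 0.06), the cyclin CCND1 (0.72, SE 0.08), the mantle cell factor SOX11 (0.54, SE 0.07) and NOTCH1 (0.70, SE 0.07) rose. PLCG2 and SOX11 share exons with other genes and are uncertain. The CD79B call was lost without resistant replicate 1 (adjusted p = 0.0502) and without resistant replicate 3 (adjusted p = 0.0585). BTK (0.13), PLCG2 (0.09) and CD79B (0.15) also lost their calls against neighbouring genes, an alternative chosen after seeing the data.

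Of 37 gene lists fixed before the data were examined, 32 had at least 5 tested genes, and 3 passed the set test (camera, preset correlation 0.01). The NF-kB target list was lower, with 18 of 27 members lower, 3 higher and 6 not past the threshold, a median log2 fold change of -0.33 and an adjusted p = 8.32e-05. The chemokine CCL22 fell from 63.0 to 5.35 CPM (-3.56, SE 0.09), the survival gene BCL2A1 from 55.4 to 10.3 CPM (-2.42, SE 0.09), the cytokine LTA by 2.40 (SE 0.13) and CXCL10 from 284 to 60.6 CPM (-2.23, SE 0.12). The list of ATF4 and integrated stress response genes was higher, with 21 of 27 members higher and 2 lower, a median of 0.63 and an adjusted p = 0.000677. CHAC1, a glutathione-degrading enzyme, had a log2 fold change of 2.27 (SE 0.17), the stress factor ATF3 2.01 (SE 0.12), the lipoprotein receptor VLDLR 1.43 (SE 0.40) and the serine synthesis enzyme PSPH 1.27 (SE 0.08). The T cell marker list was lower (adjusted p = 1.29e-05), with 5 of 7 tested members lower, 1 higher and 1 not past. CD3D fell from 34.4 to 0.518 CPM (-6.04, SE 0.11) and CD3G from 11.4 to 1.47 CPM (-2.95, SE 0.12), while CD3E rose from 10.7 to 32.8 CPM (1.62, SE 0.10). No list was past the threshold with an estimated correlation: for each of these 3 lists, adjusted p = 0.608 with an estimated correlation. Other splits of the 6 libraries into 3 and 3 gave up to 5 lists past the threshold. Such splits keep part of the group difference, so they give no measure of chance. The T cell list also missed the threshold in limma-voom (adjusted p = 0.108) and, in an alternative chosen after seeing the data, against neighbouring genes (adjusted p = 0.0632).

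**Figure D2:**
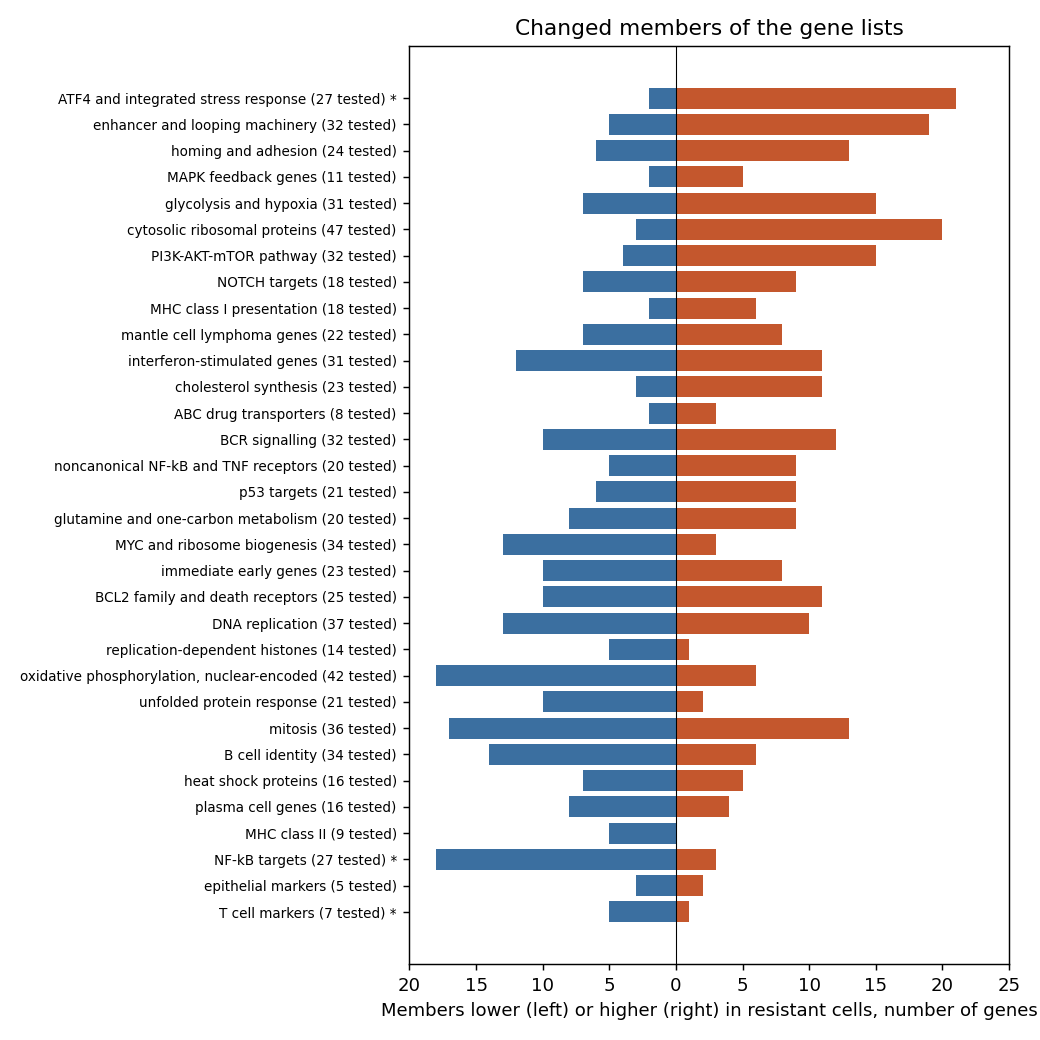
Number of members of each of the 32 tested lists that were lower (blue, left of 0) or higher (red, right of 0) in resistant cells at an adjusted p of 0.05, ordered by median log2 fold change, with asterisks on lists past the camera threshold at the preset correlation. The ATF4 list has 21 members higher and the NF-kB target list 18 lower.

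No other list passed camera in this fit, and their counts follow. For comparison, 8400 of the 12449 tested protein-coding genes passed, 4235 higher and 4165 lower, so counts near this share are not particular to a list. B cell receptor signalling genes went both ways, 12 higher and 10 lower of 32 (adjusted p = 0.841), or 23 in all when adjusted over the list alone. The inhibitory Fc receptor FCGR2B (-2.34, SE 0.16) and the BTK inhibitor protein gene SH3BP5 (-1.85, SE 0.09) fell, and LAIR1 (1.28, SE 0.07) and the kinase BLK (1.07, SE 0.06) rose. Of 23 immediate early genes, 8 were higher and 10 lower, with EGR2 at -4.29 (SE 0.36), EGR1 at -1.21 (SE 0.10) and DUSP2 at -1.28 (SE 0.07). MAPK feedback genes were 5 higher and 2 lower of 11, SPRY1 at 2.35 (SE 0.12) beside ETV1. NOTCH targets were 9 higher and 7 lower of 18, DTX1 rising from 217 to 423 CPM (0.96, SE 0.08) and HES5 falling (-1.12, SE 0.12). In the PI3K-AKT-mTOR list 15 of 32 were higher and 4 lower, 20 in all when adjusted over the list alone, with the phosphatase INPP4B at 2.34 (SE 0.16) and the adaptor IRS2 at 2.14 (SE 0.13). Noncanonical NF-kB and TNF receptor genes were 9 higher and 5 lower of 20, with TNFRSF13C (the BAFF receptor) at 1.33 (SE 0.09) and TNFRSF17 at -3.59 (SE 0.22). FCGR2B and IRS2 share exons with other genes and are uncertain.

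B cell identity genes were 6 higher and 14 lower of 34 (adjusted p = 0.158). MS4A1, which encodes CD20, fell from 1373 to 409 CPM (-1.75, SE 0.08), CD38 from 91.1 to 25.1 CPM (-1.86, SE 0.06) and FCER2 from 2.66 to 0.238 CPM (-3.47, SE 0.23). Plasma cell genes were 4 higher and 8 lower of 16, with JCHAIN falling from 93.2 to 16.3 CPM (-2.51, SE 0.13). Mantle cell lymphoma genes were 8 higher and 7 lower of 22, SP140 at -1.81 (SE 0.10; it shares exons with another gene) beside MYC and CCND1. Of 9 MHC class II pathway genes, 5 were lower and 0 higher, HLA-DMA at -1.74 (SE 0.26; uncertain, as it shares exons) from 1.46 CPM. MHC class I presentation genes were 6 higher and 2 lower of 18, 7 in all when adjusted over the list alone. The immunoproteasome gene PSMB8 rose from 32.0 to 62.9 CPM (0.97, SE 0.07) and TAPBP, which loads peptides, from 119 to 210 CPM (0.82, SE 0.06). Interferon-stimulated genes were 11 higher and 12 lower of 31, OAS3 at 2.25 (SE 0.18) and IFIT1 at -4.23 (SE 0.49).

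BCL2 family and death receptor genes were 11 higher and 10 lower of 25, 22 in all when adjusted over the list alone. The death receptor TNFRSF10B rose from 4.73 to 26.9 CPM (2.51, SE 0.11) and the BH3-only gene HRK to 3.05 CPM (2.72, SE 0.23), while FAS fell (-1.54, SE 0.13). Homing and adhesion genes were 13 higher and 6 lower of 24, with RGS1 rising from 0.509 to 15.6 CPM (4.93, SE 0.14) and the sphingosine phosphate receptor S1PR4 from 0.335 to 2.38 CPM (2.82, SE 0.23). The p53 targets were 9 higher and 6 lower of 21, SESN2 at 0.86 (SE 0.10) and TP53I3 at -1.43 (SE 0.14). ABC drug transporters were 3 higher and 2 lower of 8, 6 in all when adjusted over the list alone, and ABCB1, the multidrug efflux pump, fell from 713 to 273 CPM (-1.38, SE 0.07). Enhancer and looping machinery genes were 19 higher and 5 lower of 32 (adjusted p = 0.158), BRD2 rising from 142 to 284 CPM (0.99, SE 0.07; uncertain, as it shares exons) and LDB1 by 0.94 (SE 0.09).

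Cholesterol synthesis genes were 11 higher and 3 lower of 23 (adjusted p = 0.109), with FDFT1 rising from 386 to 1165 CPM (1.59, SE 0.07) and the regulator SREBF2 from 57.9 to 140 CPM (1.27, SE 0.06). Glycolysis and hypoxia genes were 15 higher and 7 lower of 31, 23 in all when adjusted over the list alone, MXI1 at 1.95 (SE 0.09). Nuclear-encoded oxidative phosphorylation genes were 6 higher and 18 lower of 42, COX7A2 at -1.07 (SE 0.08) and UQCRFS1 at -0.81 (SE 0.06). Glutamine and one-carbon genes were 9 higher and 8 lower of 20, glutamine synthetase, GLUL, rising from 41.4 to 130 CPM (1.65, SE 0.07). Unfolded protein response genes were 2 higher and 10 lower of 21, XBP1 falling from 129 to 67.3 CPM (-0.94, SE 0.06). Heat shock genes were 5 higher and 7 lower of 16, 13 in all when adjusted over the list alone, HSPB1 at 2.18 (SE 0.12) and HSP90AA1 at -0.95 (SE 0.09). MYC and ribosome biogenesis genes were 3 higher and 13 lower of 34, 15 in all when adjusted over the list alone, ODC1 at -0.65 (SE 0.08). Cytosolic ribosomal protein genes were 20 higher and 3 lower of 47, 21 in all when adjusted over the list alone, RPS4X at 0.81 (SE 0.07). DNA replication genes were 10 higher and 13 lower of 37, E2F1 at 1.34 (SE 0.07) and GINS3 at -0.92 (SE 0.07). Mitosis genes were 13 higher and 17 lower of 36, the spindle factor TPX2 rising from 380 to 1917 CPM (2.34, SE 0.07). Replication-dependent histones were 1 higher and 5 lower of 14, H3C4 at -0.45 (SE 0.09; uncertain, as it shares exons). For every list given here without a second count, the number adjusted over the list alone equalled that over all genes.

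Median, mean and camera direction differed in sign for 8 lists, none past the threshold: B cell receptor signalling, interferon-stimulated genes, BCL2 family and death receptors, mitosis, heat shock proteins, glutamine and one-carbon metabolism, ABC drug transporters and p53 targets. The call depended on the fit, the set test or the genes kept for 9 lists, which passed in DESeq2 and with no filter on low counts. They were B cell identity, plasma cell, MHC class I presentation, PI3K-AKT-mTOR, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, and enhancer and looping machinery. The DESeq2 fit also left out the main filter, with 23517 genes tested against 17247, so these 2 alternatives are not independent. Without parental replicate 3, the enhancer and looping list (adjusted p = 0.00389; 0.00389 to 0.894 over its alternatives) and the oxidative phosphorylation list (adjusted p = 0.0405; 0.00486 to 0.894 over its alternatives) passed. Both lists and the PI3K-AKT-mTOR list also passed against neighbouring genes, an alternative chosen after seeing the data.

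Epithelial markers were 2 higher and 3 lower of 5 (adjusted p = 0.158), CDH1 falling from 10.9 to 0.421 CPM (-4.69, SE 0.15). Too few members of 5 lists could be tested as sets. The NK cell genes PRF1 (-3.08, SE 0.34) and GZMB (2 counts in the resistant group, higher in parental cells by a ratio of 29.6, 95% counting interval 7.87 to 250) were the 2 tested of their list, and both fell. Of 3 tested myeloid genes, VCAN (-3.71, SE 0.40) and MS4A7 (-1.89, SE 0.33) fell and CD68 did not pass (-0.02, SE 0.10); MS4A7 and CD68 share exons with other genes and are uncertain. Of 4 stromal genes, 3 rose, PDGFRB from 0.459 to 8.17 CPM (4.15, SE 0.20) and COL1A1 to 1.08 CPM (1.41, SE 0.34). No erythroid or megakaryocyte gene and 0 mitochondrially encoded genes were tested.

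Neighbouring genes moved together on several chromosomes. In windows of 25 successive protein-coding genes, 58 of 395 had a median log2 fold change beyond 0.4 in size with at least 80% of genes of one sign, 36 higher and 22 lower. On chromosome 8 the window from ZNF596 to TUSC3 (GRCh37, 182137 to 15624158) had a median of 1.75 and that from CHRAC1 to FAM83H one of 1.20. The chromosome 20 window from APMAP to COMMD7 (24943561 to 31331803), which holds TPX2, had a median of 1.61. On chromosome X, the windows from TCEANC to EIF1AX (-1.04) and from CXorf38 to ZNF81 (-0.91) were lower, and that from PHF6 to MAGEA11 (0.61) was higher. Set against the median of their 50 nearest neighbours, a comparison chosen after seeing the data, BLK was at -0.61, RPL8 at -0.32 and POLA1 at 0.27, each past the threshold and opposite in sign to its fitted change, FDFT1 was at -0.08 and not past it (adjusted p = 0.36), and BTK at 0.13 (adjusted p = 0.125), CD79B at 0.15 (adjusted p = 0.0627) and PLCG2 at 0.09 (adjusted p = 0.228) were no longer past the threshold.

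**Figure D3:**
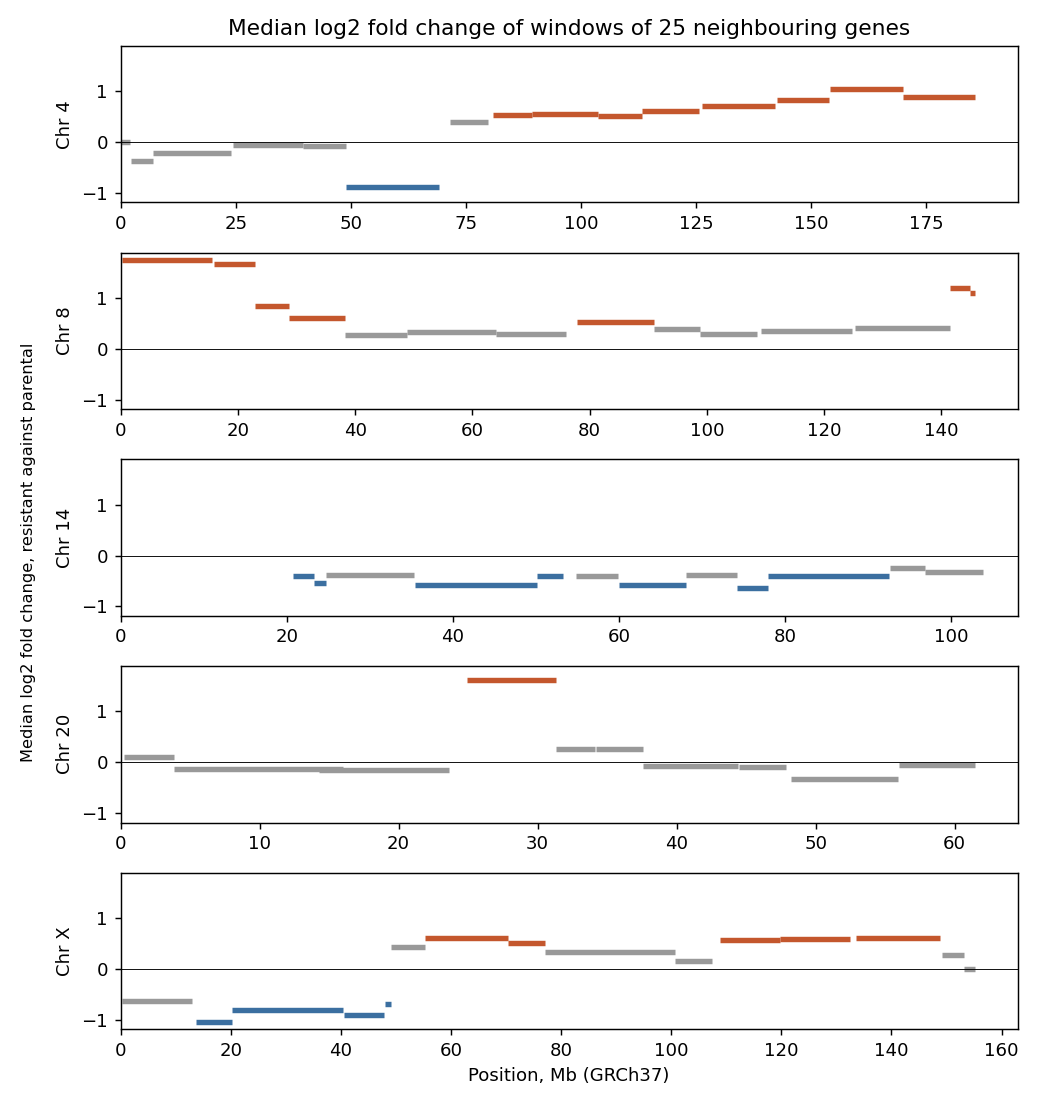
Median log2 fold change, resistant against parental, of successive windows of 25 protein-coding genes along 5 chromosomes (x axis, position in Mb, GRCh37). Windows past 0.4 in size with at least 80% of genes of one sign are red (higher) or blue (lower), others grey; the highest bar on chromosome 20 is at 1.61.

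The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Resistance and drug changed together between the groups, and their effects were not separated.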

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

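The comparison against neighbouring genes and the fit without genes that share exons were chosen after seeing the data. In the main fit 10169 of 17247 tested genes changed. The other fits with a null of 0 gave between 8243 of 14028 (without genes sharing exons) and 10887 of 35079 (no filter). Against a 1.5-fold change, a stricter null by construction, 3599 passed. The 3011 genes changed at least 2-fold numbered between 2046 of 13530 (at least 1 CPM in 3 libraries) and 3791 of 35079 (no filter). The ends of both ranges thus follow in part from the number of genes tested. Leaving out 1 library gave 9256 to 10587 genes, 3024 to 3158 genes at least 2-fold and 3 to 5 lists, 5 without parental replicate 3. The 3 lists past the threshold became 12 in DESeq2, 12 with no filter, 5 against neighbouring genes (2 of the 3 among them), 22 in fry, which does not compare a list with other genes, and 0 with an estimated correlation; apart from fry and the estimated correlation, the cause was not tested. Against their neighbours BLK (-0.61), POLA1 (0.27), FDFT1 (-0.084, adjusted p = 0.36, not past the threshold) and RPL8 (-0.32) reversed, by construction through the shift of the genes around them. Among named genes, 2780 of 2825 values under an alternative kept direction and side of the threshold 41, of 13 genes, kept direction but lost the call, and the 4 above reversed. The labels do not say whether the replicate numbers pair the samples. The correlations of same-numbered deviations were 0.49, -0.44 and -0.03, and not every sample correlated best with its own number. The highest, 0.555, joined parental replicate 3 and resistant replicate 2. Pairing by number was thus not seen, but with 3 samples per group it cannot be excluded. With the replicate number as a block, 9727 genes, 2992 genes at least 2-fold and 3 lists passed. Depth limits genes near the floor of 3 counts.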

Other observations

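Families in this and the next paragraph were picked after their values were seen, and 8400 of all 12449 tested protein-coding genes passed the threshold. All 7 tested Fc receptor-like genes, which encode immunoglobulin-like receptors of B cells, were lower in resistant cells: FCRL5 fell from 416 to 130 CPM (log2 fold change -1.68, SE 0.07), FCRL3 from 320 to 130 CPM (-1.31, SE 0.07) and FCRLA from 136 to 49.7 CPM (-1.46, SE 0.09). FCRL1, FCRL2, FCRL3, FCRL4 and FCRL5 lie side by side on chromosome 1 (157483167 to 157789895), and FCRLA lies beside FCRLB on the same chromosome. Neighbouring genes moved together elsewhere, so these 7 need not be separate changes. Of 24 interleukin receptor genes, 12 were higher and 7 lower. IL6R fell from 52.2 to 7.83 CPM (-2.74, SE 0.08) and IL5RA from 22.5 to 0.938 CPM (-4.57, SE 0.13), whereas IL10RB rose from 10.5 to 33.9 CPM (1.70, SE 0.08; it shares exons with another gene). Of 5 tested killer lectin-like receptor genes, 4 were lower, KLRC3 at -4.96 (SE 0.27), all 4 uncertain because of shared exons. These 4 also lie side by side on chromosome 12.

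Of 24 receptor tyrosine kinase genes, 13 were higher, 11 of them at least 2-fold, and 7 lower. MET rose from 1.29 to 26.3 CPM (4.35, SE 0.13), FGFR3 from 0.393 to 7.15 CPM (4.16, SE 0.19) and IGF1R from 8.43 to 34.1 CPM (2.02, SE 0.09), and EPHB2 fell (-1.97, SE 0.14). The NOTCH ligands JAG2 (2.76, SE 0.11) and DLL3 (1.59, SE 0.12) rose beside JAG1. Of 12 genes known as targets of the oxysterol receptor LXR, 8 were higher and 3 lower: ABCG1 rose from 0.444 to 22.4 CPM (5.65, SE 0.13) and SCD from 762 to 1635 CPM (1.10, SE 0.07), while CD36 fell from 137 to 35.5 CPM (-1.95, SE 0.10). X-linked cancer-testis genes were 9 higher and 1 lower of 12, MAGEA4 at 5.18 (SE 0.28) and MAGEB2 at 4.32 (SE 0.20), and MAGEB1 at -2.95 (SE 0.19). JAG1, JAG2, SCD and MAGEB1 share exons with other genes and are uncertain.

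The tests below were written down before their results were seen, except the count of genes that share exons with DDX3X and the shifts fitted from length, GC content and expression. Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 10169 genes, 3011 genes at least 2-fold and 3 lists. The highest of the other splits gave 0, 0 and 5. As large a result came from 1, 1 and 6 of the 10 splits, the real one included. Every other split puts libraries of both groups on each side, so the group difference enters its spread and its 0 genes decide nothing. Part of that difference also remains between its sides, so its lists give no measure of chance either. The number of lists thus decides nothing on chance.

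Neighbouring genes changed together in 58 of 395 windows of 25 genes, against at most 3 windows in 100 shuffled gene orders. Such windows were 14.7% of all windows and held 17.6% of the changed genes in windows (1179 of 6691). That share is limited by the cut, because so few windows could not hold most of the changed genes whatever their shifts. Windows under the cut moved too, such as that from EIF3E to FAM91A1 on chromosome 8 (median 0.35, 88% of genes of one sign). The share of changed genes on shifted stretches stays open. The pattern is consistent with stretches of chromosome present in more or fewer copies in the resistant cells, as a hypothesis, because the test could have come out within the shuffled range. DNA copies were not measured here, and domains of shared regulation stay open.

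DDX3X, with a log2 fold change of -4.81, lies on a stretch of X with lower expression. Loss of a stretch reaching 1 Mb to either side would take its neighbours as far. The median of the 14 tested neighbours within 1 Mb, pseudogenes included, was -0.66 (95% bootstrap interval -0.94 to -0.39, neighbours taken as independent). Pseudogene values are uncertain, as near-identical copies can take each other's fragments. The protein-coding neighbours CXorf38 (-0.91), CASK (-0.78), MED14 (-0.64), USP9X (-0.62) and GPR34 (-0.24, not past the threshold) fell far less than DDX3X. These values argue against such a loss as the whole cause. Past the threshold, 8 neighbours were lower, with the protein-coding genes GPR82 lowest at -3.46 (SE 0.63) and ATP6AP2 at -1.45 (SE 0.09). The 1 higher was the pseudogene YWHAZP10 (0.40, SE 0.11). A loss too short to take in most neighbours would leave the median unchanged, and it was not tested. Another gene that shares its exons could not take fragments from it, because a fragment was counted for every gene it overlapped. That 0 genes of the annotation used for the counts overlap its exons on the same strand thus adds nothing to this. A change limited to this gene may lie behind the rest, and neither its DNA nor its splicing was examined here.

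The NF-kB list (median -0.33) and the ATF4 list (median 0.63) could follow gene length and GC content or the shifted stretches. After a fit on length, GC content and expression the medians were -0.37 (95% bootstrap interval -0.82 to -0.19) and 0.58 (0.13 to 0.76), and after subtracting the median of 50 neighbours they were -0.27 (-0.49 to -0.08) and 0.52 (0.32 to 0.98). The fit explained little (R squared 0.023): its shift ran from -0.16 to 0.36 between the 5th and 95th percentiles of genes, with a median of 0.05 in the NF-kB list and 0.07 in the ATF4 list. The intervals treat list members as independent and may be too narrow. Camera estimated correlations between members of 0.125 in the NF-kB list and 0.114 in the ATF4 list. The medians themselves kept most of their size, which argues against either explanation as the whole cause of the lists. A response to the drug and a lasting difference of the resistant cells stay open, since drug and resistance were changed together. The calls of both lists are lost in camera with an estimated correlation (adjusted p = 0.608). The splits of the libraries could not decide on chance for the lists, so chance stays open as well.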
